A study of Mus musculus with 4 samples.

How the data were processed

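Each of the 4 samples was hybridised to 1 array, and the labels put 2 in the CD11b-positive and 2 in the CD11b-negative fraction; replicate numbers follow the order of deposit and only name an array. The deposited values are intensity values, 1 signal per probe set on a linear scale, made with MAS5 and Affymetrix Expression Console per the submitters' processing notes; versions, settings and scaling target are not given in the sources used here. Of 45101 probe sets, 64 are controls, 34945 name 1 gene, 932 name several and 9160 are unnamed here. Gene symbols came from the platform annotation; 34741 of the gene identifiers were found in the gene table of assembly GRCm38.p6, used for names only, and 0 symbols needed updating. The array names no genome build, so no coordinates are given.

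Before the data were examined, the plan took the deposited signals as already scaled between arrays. They were not: the 2% trimmed means were 48.5 and 70.02 in the CD11b-negative and 73.7 and 90.2 in the CD11b-positive arrays, so quantile normalization, listed beforehand, became the main setting before any model was fitted, and the deposited scaling was tried beside it. Array medians were 14.7 and 16.1 in the CD11b-negative and 18.3 and 17.5 in the CD11b-positive arrays. A pseudocount of 3, the 20th percentile of all signals, was added before log2, so fold changes understate differences of weak genes. Probe sets with a mean above the 40th percentile were kept (a signal of about 9.51), with the brightest probe set per gene among those that name 1 gene. The 12645 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05). An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is printed for single genes. Beside it, genes were counted whose lower array in one fraction was at least 2-fold above the higher array of the other.

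The plan stated that the labels name no batch, while their labelling protocols name 2 kits, each used for 1 array of both fractions. The 2 styles of sample title, planned as a replicate block, follow these kits exactly, so that planned fit is the one with the labelling kit as a block; the fit without it stays the main one, as planned. Deviations from the fraction means of arrays prepared with the same kit correlated across genes (r = 0.387). The blocked fit leaves 1 residual degree of freedom per gene and rests on a prior of 25.6 degrees of freedom shared across genes. Tested on 5 simulated data sets per fold size for this comparison, with kit differences as observed and 200 genes changed, the model without the block recovered 0% of 2-fold and 45.0% of 4-fold changes, with 0 false calls, among about 12692 genes. The blocked model recovered 63.6% and 92.03%, with 8.2 and 14.8 false calls per data set. The simulated noise was normal, independent between genes, and had the spread that the blocked fit expects at each signal level. Since the blocked model assumes just that, these rates are likely too favourable to it and do not vouch for its calls on the real arrays.

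Lists of genes were fixed before the data were examined: plasma cell, immunoglobulin, mature B cell, germinal centre, mitosis, DNA replication, endoplasmic reticulum stress and secretion, integrins and homing, Toll-like receptors and NF-kB, cytokine receptors and survival, secreted cytokines, interferon response, B-1 lineage, glycolysis, TCA cycle and respiratory chain, ribosome biogenesis, immediate early, macrophage with monocyte and dendritic cell, granulocyte and mast cell, T cell with NK and innate lymphoid cell, epithelial, stroma, and red cell with platelet genes. Of 821 entries in these 23 lists, 746 matched a gene on the array; the others are not analysed here. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists. Camera compares a list with all other genes; fry tests whether its genes move one way.

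Named genes followed a rule fixed beforehand: Itgam, Itgb2, Igha, Jchain, Mki67, Prdm1, Xbp1, Sdc1, Myd88 and Il10ra always; in each direction the 12 largest changes among genes that passed, filled, since none did, by smallest p among genes whose arrays did not overlap and whose fraction means differed at least 2-fold (the reading taken of that rule); and up to 4 members per list by smallest p. Signals given are quantile-normalized. The alternatives were pseudocounts of 1 and 12, the deposited scaling, centring on the median, no low-signal filter or one at the 70th percentile, the mean of all probe sets of a gene, leaving out probe sets whose name marks possible cross-hybridisation, the block, no trend, a fit per probe set, and leaving out each array in turn. Scaling to a common 2% trimmed mean and cyclic loess were added after seeing the data. Leaving out 1 array leaves the kits uneven between the fractions, so part of the kit difference enters the values of those refits.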

Results

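Gene expression was measured on 4 Affymetrix 3' expression arrays hybridised with RNA of IgA-positive cells from the small intestine of female BALB/c mice. IgA is the antibody class secreted into the gut, and its main producers there are plasma cells of the lamina propria. The cells had been separated by surface CD11b, the integrin alpha M chain best known from myeloid cells, into a CD11b-positive and a CD11b-negative fraction, with 2 arrays of each. According to the labels, 1 array of each fraction was prepared with the One-Cycle kit from 1 µg of RNA and 1 of each with the 3' IVT Express kit from 0.1 µg, so each labelling kit holds both fractions. Nothing in the labels says whether arrays of a fraction came from separate animals or sorts, so the p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value. Pearson's r between arrays, across 12645 genes, which are not independent replicates, ran from 0.933 to 0.958. Between the fractions within a kit r was 0.954 and 0.958. Within a fraction it was 0.956 for the CD11b-positive and 0.940 for the CD11b-negative arrays.

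The comparison asks how IgA-positive cells that carry CD11b differ in expression from those that do not. Itgam, the gene of CD11b, had a mean signal of 149 ± 56.6 (SD, n = 2) in the CD11b-positive and 22.1 ± 8.88 (SD, n = 2) in the CD11b-negative fraction, a 6.04-fold difference that goes with the labels of the sort. Genes of cell division and of DNA replication stood higher in the CD11b-positive fraction, and genes of gut epithelium and of the immediate early response stood lower. These 4 lists passed by camera with a preset correlation between genes. With an estimated correlation, however, the adjusted p was 0.366 for each, and by fry it was 0.188 to 0.269. The test with an estimated correlation has only the 2 residual degrees of freedom of the fit, so it had little power after adjustment over 23 lists. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05 (smallest adjusted p = 0.306, for Grn and Slpi), while 397 higher and 445 lower genes had an unadjusted p under 0.05. Some genes pass such an unadjusted cutoff by chance. The fractions gave 842 in all, the split of the 4 arrays by labelling kit 1759 and the remaining split into pairs 98. With the labelling kit as a replicate block, the same limma model called 472 genes higher and 524 lower in the CD11b-positive fraction, out of 12645 tested. Adjusted p-values given below "with the block" come from that fit.

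**Figure D1:**
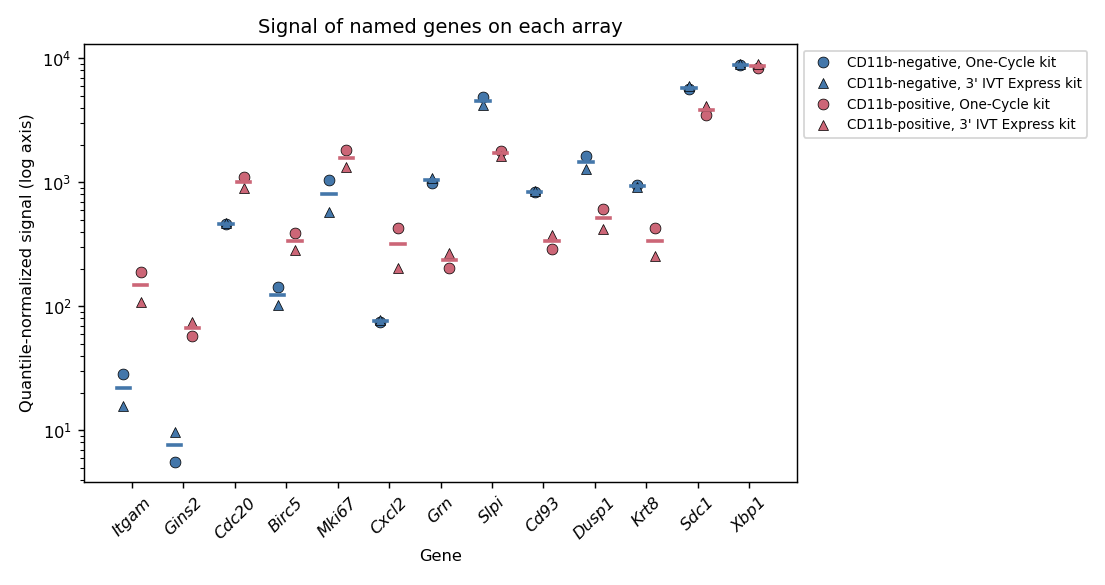
Quantile-normalized signal (log axis) of 13 named genes on each of the 4 arrays, with points for single arrays, shapes for the labelling kits and bars for the mean of the 2 arrays of a fraction. Itgam lies at 188.8 and 108.8 in the CD11b-positive against 28.3 and 15.8 in the CD11b-negative arrays, and Xbp1 near the top of the signal range, where quantile normalization draws the arrays together.

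By a fixed rule of size, 43 genes were higher and 49 lower in the CD11b-positive fraction by at least 2-fold between the nearest arrays of the 2 fractions. The split depended on how the arrays were scaled: it was 179 higher and 15 lower on the signals as deposited, 102 and 28 after centring on the median, 27 and 75 after scaling to a common trimmed mean, and 41 and 50 after cyclic loess. Arrays of the 2 fractions did not overlap for 35.5% of genes, where chance gives 33.3% for 2 arrays against 2. On simulated data for this comparison the rule found 9.04% of 2-fold and 85.01% of 4-fold changes, with 25.2 and 29.2 false calls per data set.

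Genes named by the fixed rule were described by value, since none passed the limma test without the block. All 12 in each direction passed it with the block, but the same 4 arrays chose them, so this is no independent support. Of the 12 higher genes, Gins2 and Esco2 had mean CD11b-negative signals below the low-signal filter, so no fold is given for them; the other 10 ran from 2.13-fold to 6.04-fold. Of the 12, 5 belong to the mitosis or DNA replication lists, among them Gins2, a subunit of the replicative helicase (57.7 and 75.02 in the CD11b-positive against 5.53 and 9.61 in the CD11b-negative arrays, adjusted p = 2.45e-05 with the block), Cdc20, an activator of the anaphase-promoting complex (2.13-fold, adjusted p = 1.82e-07 with the block), and Birc5, the chromosomal passenger protein survivin (2.70-fold, adjusted p = 2.44e-07 with the block). Cenpi, Cenpl, Timeless and Cep55, which also act in chromosome replication, segregation or cytokinesis, were 3.10-fold, 3.14-fold, 2.86-fold and 2.69-fold higher. Esco2, an acetyltransferase of sister chromatid cohesion, had signals of 65.4 and 50.6 against 8.48 and 10.4. Cxcl2, a chemokine for neutrophils, was 3.80-fold higher, at 318 ± 162 against 75.8 ± 2.38 (SD, n = 2 each). The 12 lower genes ran from 2.32-fold to 4.40-fold. Grn, which encodes the secreted growth factor progranulin, was 4.40-fold lower (236 ± 45.1 against 1040 ± 63.2, SD, n = 2 each), and Slpi, a secreted inhibitor of leukocyte proteases, was 2.63-fold lower (1720 ± 104 against 4537 ± 502, SD, n = 2 each). Cd93, a surface glycoprotein found on some plasma cells, was 2.51-fold lower. Agr2 and Defa31, genes of mucus-secreting and Paneth cells, were 3.89-fold and 2.58-fold lower. Of these 24 genes, Aif1l and Tspan8 also had a probe set above the low-signal filter that went the other way. Where other probe sets above the filter went the same way, their size could differ. Timeless was at 0.75 against 1.52 log2 for the probe set used, and Cdc20 at 0.83 and 1.48 against 1.09. Cd93 was at -0.26, -0.84 and -1.20 against -1.33.

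Of 42 mitosis genes, 39 were higher in the CD11b-positive array of both kits, and their median log2 difference was 1.06 (quartiles 0.77 and 1.28). The list rose by camera (adjusted p = 1.81e-31), but not with an estimated correlation between its genes (adjusted p = 0.366) or by fry (adjusted p = 0.267). Adjusted over the list alone, 28 members were higher, against 0 over all genes; with the block these counts were 39 and 31. Mki67, a marker of cycling cells, was 2.00-fold higher (1579 ± 338 against 810.8 ± 327, SD, n = 2 each, adjusted p = 2.26e-07 with the block). Its log2 difference was 1.00, with 0.80 and 1.21 within the kits, and 0.56 without CD11b-negative replicate 2. Cdca8 was 2.37-fold and Ube2c 2.24-fold higher. The 41 DNA replication genes had a median of 0.79 (camera adjusted p = 2.23e-21, adjusted p = 0.366 with an estimated correlation), and 35 were higher with both kits; adjusted over the list alone 18 were higher, and 23 over all genes with the block. Rrm2, a subunit of ribonucleotide reductase, was 2.00-fold, Mcm3 2.49-fold and Gmnn 2.09-fold higher; with the mean of all probe sets Mcm3 fell from 1.32 to 0.71 log2. Ribosome biogenesis genes had a median of 0.19 over 40 genes (camera adjusted p = 0.00981, adjusted p = 0.494 with an estimated correlation), with 7 higher with the block, among them Npm1 (1.32-fold) and Ncl (1.31-fold). Without CD11b-positive replicate 1 that median was 0.0036 (camera adjusted p = 0.595), and without CD11b-negative replicate 2 it was 0.09 (camera adjusted p = 0.245).

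**Figure D2:**
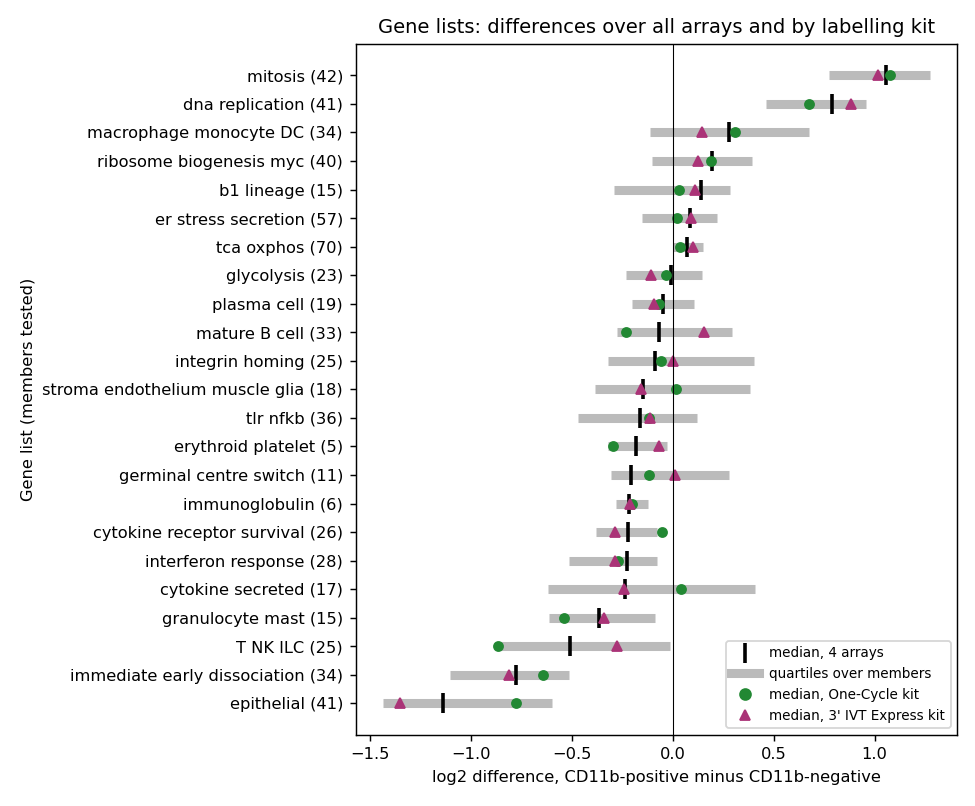
Median log2 difference, CD11b-positive minus CD11b-negative, of the 23 gene lists over all 4 arrays (bars), within each labelling kit (points), and the quartiles over list members (grey), with the number of members tested in parentheses. Mitosis lies at 1.06 and epithelial genes at -1.14.

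Of 41 epithelial genes, 37 were lower with both kits, with a median of -1.14 (quartiles -1.44 and -0.60), and -0.69 without CD11b-positive replicate 2. The list fell by camera (adjusted p = 1.74e-25), but not with an estimated correlation (adjusted p = 0.366) or by fry (adjusted p = 0.269). Adjusted over the list alone 24 were lower, and 26 over all genes with the block. Krt8, a keratin of simple epithelia, was 2.83-fold lower, Cldn7, a tight junction protein, 2.75-fold, and Reg3b, an antibacterial lectin, 2.32-fold. Genes of the immediate early response, which cells switch on within minutes of a stimulus and also during tissue dissociation, had a median of -0.78 over 34 genes (camera adjusted p = 1.76e-19, adjusted p = 0.366 with an estimated correlation), and 30 were lower with both kits. Adjusted over the list alone 14 were lower, and 26 over all genes with the block. Dusp1, a MAP kinase phosphatase, was 2.86-fold, Junb 2.43-fold, Ppp1r15a 1.91-fold and Ier5 1.77-fold lower. Markers of T cells, NK cells and innate lymphoid cells had a lower median as well (-0.51 over 25 genes, camera adjusted p = 0.00535, adjusted p = 0.550 with an estimated correlation), and 14 were lower with both kits. Their median was -0.87 with the One-Cycle kit and -0.27 with the 3' IVT Express kit, against -0.78 and -1.35 for the epithelial genes. Among these markers, Ccl5 was 2.07-fold and Nkg7 2.06-fold lower. Ccl5 was at -1.05 log2, with -1.34 and -0.76 within the kits. It was at -0.37 without CD11b-negative replicate 1, -1.72 without CD11b-negative replicate 2 and -0.65 without CD11b-positive replicate 2. That call ended without CD11b-negative replicate 1 (median -0.17, camera adjusted p = 0.684) and without CD11b-positive replicate 2 (median -0.16, camera adjusted p = 0.430). Without the other 2 arrays the median was -0.81 (CD11b-positive replicate 1) and -0.98 (CD11b-negative replicate 2). The ratio of 3' to 5' signal of the beta-actin control probe sets, which rises as RNA is shortened, was 1.90 and 1.84 in the CD11b-negative and 1.43 and 1.61 in the CD11b-positive arrays; that of Gapdh was 0.685 and 0.704 against 0.682 and 0.710.

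**Figure D3:**
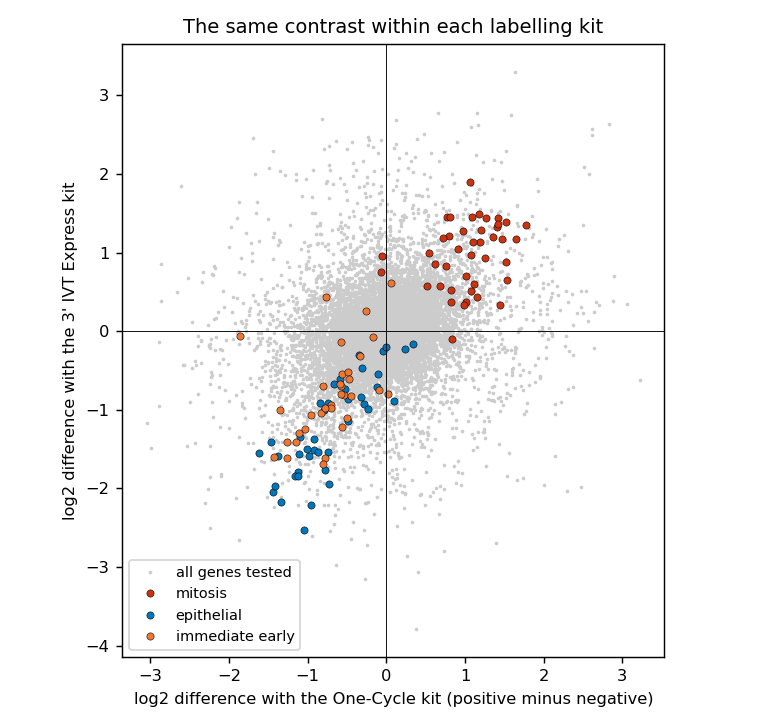
Log2 difference, CD11b-positive minus CD11b-negative, of each of 12645 genes with the One-Cycle kit (x axis) against the 3' IVT Express kit (y axis), with mitosis, epithelial and immediate early genes coloured. The 2 differences share no array, and across genes Pearson's r was 0.275.

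The plasma cell list did not pass (median -0.05 over 19 genes, camera adjusted p = 0.468). It passed as lower after cyclic loess (median -0.16, camera adjusted p = 0.0200; on quantile-normalized signals with an estimated correlation 0.550), and with the block 2 members were lower and 2 higher. Eaf2 was 1.33-fold and Sub1 1.32-fold higher (adjusted p = 0.00280 and 0.00400 with the block), and Tnfrsf13b was 1.26-fold lower (0.0194). Sdc1, the plasma cell surface proteoglycan CD138, was 1.52-fold lower in the CD11b-positive fraction (3814 ± 483 against 5783 ± 223, SD, n = 2 each; adjusted p = 8.98e-06 with the block), and Prdm1, the regulator Blimp-1, stood at 808 ± 200.2 against 915 ± 198 (SD, n = 2 each; adjusted p = 0.355 with the block). Igha, the IgA heavy chain, and Jchain, the joining chain of secreted antibodies, ranked between 1 and 7 of 45037 probe sets on every array, at the top of the signal range, where quantile normalization nearly fixes the values. Their log2 differences were -0.10 and 0.10. On leaving out 1 array, Igha ran from -0.17 to -0.04 and Jchain from 0.01 to 0.19. The 2 other probe sets of Igha gave -0.64 and -0.26, and the mean of all 3 gave -0.33. Under the 4 other scalings Igha stayed lower, from -0.56 to -0.67 relative to all genes, and Jchain, on the same relative scale, turned lower, from -0.31 to -0.42. Xbp1, a transcription factor of plasma cells that ranked between 21 and 32, had mean signals of 8718 ± 399 in the CD11b-positive and 8931 ± 143 in the CD11b-negative fraction (SD, n = 2 each) and a log2 difference of -0.04. Under the 4 other scalings this was -0.32 to -0.44 relative to all genes, and with the mean of all probe sets it was -0.19. The highest deposited signal was 12072.5 and 13778.1 in the CD11b-negative and 10969.6 and 13711.5 in the CD11b-positive arrays. It was thus not higher in the CD11b-positive array of either kit, while the trimmed means were. Scaling by the bulk of genes can therefore lower genes at the top of the range there, whatever their true level. The immunoglobulin list had a median of -0.22 over 6 genes (camera adjusted p = 0.0157, adjusted p = 0.366 with an estimated correlation), with Ighg3 2.07-fold lower (adjusted p = 5.92e-08 with the block) and 3 members lower with the block. Ighg3, at -1.05 log2, was at -0.54 without CD11b-positive replicate 1, -0.62 without CD11b-negative replicate 2 and -0.55 with the mean of all probe sets. The list median was -0.37 without cross-hybridising probe sets (camera adjusted p = 0.00355) and -0.31 with the mean of all probe sets (0.0166). Relative to all genes, the list median was -0.56 on the signals as deposited and after centring (camera adjusted p = 0.0147 and 0.0121). It was -0.63 with a common trimmed mean (1.67e-06) and -0.67 after cyclic loess (1.90e-07). Because Igha and other members lie near the top of the range, the list values under these 4 scalings do not show lower immunoglobulin expression. Without the low-signal filter the median stayed at -0.22, with a camera adjusted p of 0.0622. Without CD11b-negative replicate 1 it was -0.16 (0.0624) and without replicate 2 -0.22 (0.221).

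Among innate signalling genes, the Toll-like receptor and NF-kB list had a median of -0.16 over 36 genes (camera adjusted p = 0.0156, adjusted p = 0.366 with an estimated correlation). With the block 8 members were lower and 0 higher, including inhibitors that NF-kB itself induces: Nfkbia was 1.68-fold and Tnfaip3 1.69-fold lower. The call ended on leaving out any of the 4 arrays (camera adjusted p = 0.0586 to 0.0665). The median was then -0.06 without CD11b-negative replicate 1, -0.11 without CD11b-positive replicate 1, -0.19 without CD11b-negative replicate 2 and -0.23 without CD11b-positive replicate 2. The call also ended on the signals as deposited and after median centring (-0.14 on each, camera adjusted p = 0.287 and 0.220). Myd88, the adaptor of most Toll-like receptors, stood at 168 ± 24.4 against 145 ± 11.8 (SD, n = 2 each; adjusted p = 0.581 with the block). Il10ra lay below the low-signal filter, with signals of 9.89 and 16.5 in the CD11b-positive and 1.93 and 14.9 in the CD11b-negative arrays. Itgb2, the beta chain that pairs with CD11b, stood at 1455 ± 8.29 against 1789 ± 181 (SD, n = 2 each; adjusted p = 0.0531 with the block).

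Of the other lists that passed by camera, cytokine receptor and survival genes had a median of -0.22 over 26 genes (adjusted p = 0.00637), with Tnfrsf13c, the BAFF receptor, 1.83-fold and Bcl2 1.88-fold lower. Bcl2, at -0.91 log2, was at -0.46 with the mean of all probe sets, -0.45 without cross-hybridising ones, -0.41 without CD11b-negative replicate 1, -1.42 without CD11b-negative replicate 2 and -0.56 without CD11b-positive replicate 2. Interferon response genes had a median of -0.23 over 28 genes (adjusted p = 0.0157) and granulocyte and mast cell genes -0.37 over 15 (adjusted p = 0.0157), with Prg2, an eosinophil granule protein, 2.69-fold lower. Macrophage, monocyte and dendritic cell genes had a median of 0.28 over 34 genes (adjusted p = 0.0490, and 0.166 with the block): Il1b was 2.86-fold (log2 difference 1.52, and 0.91 without CD11b-positive replicate 1) and Itgax 1.81-fold higher, and Cst3 1.69-fold lower. With an estimated correlation their adjusted p-values were 0.407, 0.366, 0.470 and 0.546. Each of these 4 lists lost its call on leaving out at least 1 array. Cytokine receptors had a median of -0.22 (adjusted p = 0.245) without CD11b-negative replicate 2 and -0.17 (0.168) without CD11b-positive replicate 2. Granulocyte genes stayed at -0.33 (0.392) without CD11b-negative replicate 1 and -0.35 (0.388) without CD11b-positive replicate 2. Interferon genes fell to -0.13 (0.379) without CD11b-positive replicate 1 and -0.12 (0.398) without CD11b-negative replicate 2. Macrophage genes fell to 0.17 (0.245) without CD11b-negative replicate 2 and turned to -0.02 (0.624) without CD11b-positive replicate 1. Other arrays moved medians away from 0: cytokine receptors to -0.33 without CD11b-positive replicate 1, granulocyte genes to -0.57 without CD11b-positive replicate 1 and -0.58 without CD11b-negative replicate 2, and macrophage genes to 0.50 without CD11b-positive replicate 2. Cytokine receptors also lost their call on the signals as deposited and after median centring (-0.20 on each, 0.116 and 0.109) and with the mean of all probe sets (-0.09, 0.101). Interferon genes lost theirs with the mean of all probe sets (-0.14, 0.0711), and granulocyte genes without the low-signal filter (-0.24, 0.349). Macrophage genes lost theirs on the signals as deposited (0.19, 0.0585) and with a common trimmed mean (0.18, 0.110). At the same median of 0.28, they lost it with the filter at the 70th percentile (0.412) and without cross-hybridising probe sets (0.0624). The 10 remaining lists that did not pass, apart from plasma cells, had medians of 0.07 (respiratory chain and TCA cycle, adjusted p = 0.0552, and 0.0308 with the block), 0.09 (endoplasmic reticulum stress and secretion), 0.14 (B-1 lineage), -0.01 (glycolysis), -0.07 (mature B cells), -0.09 (integrins and homing), -0.15 (stroma), -0.18 (red cells and platelets), -0.20 (germinal centre) and -0.24 (secreted cytokines), with camera adjusted p-values from 0.402 to 0.987 for all but the first. The respiratory chain list passed on the signals as deposited (median 0.20, adjusted p = 0.00328), after median centring (0.20, adjusted p = 0.00113) and with a common trimmed mean (0.13, adjusted p = 8.76e-05). It also passed without the low-signal filter (0.07, adjusted p = 0.0390) and without cross-hybridising probe sets (0.08, adjusted p = 0.0226). Without CD11b-positive replicate 2 its median was 0.0052 (adjusted p = 0.402), and without CD11b-positive replicate 1 it was 0.12 (0.0895). Endoplasmic reticulum genes passed after median centring (0.16, adjusted p = 0.0393) and with a common trimmed mean (0.09, adjusted p = 0.0273). Stromal genes passed on the signals as deposited and after centring (-0.34 on each, adjusted p = 0.0335 and 0.0451). Red cell genes passed without the filter (-0.42, adjusted p = 0.0390) and mature B cell genes without CD11b-negative replicate 2 (-0.26, adjusted p = 0.00821). On leaving out 1 array, medians ran from -0.22 to -0.04 for stromal and from -0.35 to -0.06 for red cell genes. On quantile-normalized signals with an estimated correlation, these 5 lists had adjusted p-values of 0.407 (respiratory chain, and 0.597 with the block), 0.544, 0.550, 0.550 and 0.697.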

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

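The analysis by gene left out probe sets without a single gene name. Of 4612 such probe sets above the low-signal filter, 10 were at least 2-fold higher and 15 at least 2-fold lower in the CD11b-positive fraction, without overlap of the arrays. They are not named here, and no explanation was tested.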

How the results depend on the processing

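Scaling to a common trimmed mean and cyclic loess were chosen after seeing the data. The labelling kit as a replicate block raised the limma calls from 0 to 472 higher and from 0 to 524 lower genes; the kit difference it removes from the spread is its construction. Leaving out 1 array gave 0 to 2 higher and 0 to 22 lower genes, the most without CD11b-positive replicate 1; every other alternative, the fit per probe set included, gave 0 of each. Where 1 array is left alone in a fraction, it is assumed to vary like the other fraction.

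The count of genes at least 2-fold higher, 43, was 65 with a pseudocount of 1, 14 with one 4 times as large, 179 on the deposited scaling, 102 after median centring, 115 without the filter, 9 with the filter at the 70th percentile, and 27 with a common trimmed mean. The count lower, 49, was 21 with the larger pseudocount, 15, 28 and 141 on the deposited scaling, after centring and without the filter, 21 at the 70th percentile, 31 with the mean of all probe sets and 75 with a common trimmed mean. Leaving out 1 array gave 91 to 313 higher and 162 to 339 lower, since fewer arrays have to be apart. The deposited scaling and median centring moved the median of all genes by 0.42 and 0.23 log2, and values for lists and genes are relative to that; the cause of the other moves was not tested.

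The mitosis (1.06), DNA replication (0.79), epithelial (-1.14) and immediate early (-0.78) lists kept their direction and a camera adjusted p under 0.05 in 16 of 16 refits, the block and each left-out array included (medians 0.80 to 1.31, 0.67 to 0.92, -1.31 to -0.69 and -0.83 to -0.60). With an estimated correlation each had an adjusted p of 0.366, and with fry 0.267, 0.188, 0.269 and 0.188, at the same medians of 1.06, 0.79, -1.14 and -0.78. The estimated correlations were 0.518, 0.134, 0.427 and 0.0958, above the preset 0.01, so the p-values of camera with the preset are likely too small. They rest on 2 residual degrees of freedom and on residuals that still hold the kit difference, so they are imprecise and may be raised by it. With the block, camera with an estimated correlation gave adjusted p-values of 0.522, 0.522, 0.554 and 0.522. That test has only 2 residual degrees of freedom, and 1 with the block. The Toll-like receptor and immunoglobulin lists had estimated correlations of -0.0277 and -0.164, below the preset. Their camera adjusted p-values still rose from 0.0156 and 0.0157 to 0.366. A rise of p with an estimated correlation therefore does not reflect correlation alone.

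Some lists reversed. Glycolysis did so on the deposited scaling and after median centring (0.0271 on each), with the mean of all probe sets (0.11) and without cross-hybridising probe sets (0.0063). On leaving out 1 array, medians ran from -0.0253 to 0.28 for B-1 lineage, from -0.47 to 0.10 for secreted cytokines, from -0.0130 to 0.10 for endoplasmic reticulum, from -0.21 to 0.16 for germinal centre, from -0.0232 to 0.50 for macrophage, from -0.26 to 0.0550 for mature B cell and from -0.0671 to 0.0030 for plasma cell genes. Jchain reversed on the deposited scaling and after centring (-0.31), with a common trimmed mean (-0.38) and cyclic loess (-0.42). On leaving out 1 array Prdm1 ran from -0.44 to 0.0700 and Xbp1 from -0.10 to 0.0119. Leaving out 1 array sets the kits unevenly against the fractions, so part of the kit difference enters these values. Within the kits Prdm1 was at -0.15 and -0.22 and Xbp1 at -0.07 and -0.0052, lower in both. How much of each reversal this explains was not tested. Signal near background limits weak genes, and the top of the range limits Igha, Jchain, Mzb1 and Xbp1.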

Other observations

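All tests of explanations in this part were chosen after the results were seen, and the genes named here that the fixed rule does not cover were chosen after their values were seen. The gut-homing receptors Ccr9 and Ccr10 differed by 0.06 ± 0.21 and -0.09 ± 0.16 log2 (SE, n = 2 arrays each), CD11b-positive minus CD11b-negative. Tnfrsf17, the receptor BCMA of plasma cells, differed by -0.06 ± 0.14. These SEs come from the fit without the block and hold the kit difference. With the block they were 0.09 for Ccr9, 0.10 for Ccr10 and 0.09 for Tnfrsf17 (limma adjusted p = 0.805, 0.701 and 0.775). With 2 arrays per fraction these values do not exclude a difference. Some other genes differed in limma with the labelling kit as a block. S1pr1, a receptor for exit from tissue, was higher by 0.85 log2 (adjusted p = 0.00678) and Spn (CD43) by 0.71 (adjusted p = 2.68e-04). Slc3a2, an amino acid transporter subunit, was lower, at -0.85 (adjusted p = 1.89e-07). Hspa1a, a heat shock protein, was at -1.27 with one kit and -1.62 with the other.

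The mitosis genes were higher in the CD11b-positive fraction. Array scaling, if it bent with the signal level, would move genes of the same level alike. On the deposited scaling the 200 genes nearest in level to each mitosis gene had medians of 0.15 to 0.60 log2, and the mitosis genes lay above these by a median of 1.03 (quartiles 0.74 and 1.29), 42 of 42 of them higher. A labelling-kit difference would not appear within a kit, where the medians were 1.08 and 1.02 (lower quartiles 0.81 and 0.62). Dilution of plasma cell RNA by other cells in the CD11b-negative arrays would raise plasma cell genes as well; the 13 of them below the top of the range had a median of -0.0643 (quartiles -0.22 and 0.14). A larger cycling share among CD11b-positive IgA cells and dividing cells of another type both stay open; neither was tested.

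The epithelial genes were lower in the CD11b-positive fraction. Epithelial cells carried into the CD11b-negative arrays would bring all their abundant transcripts: of the 26 list genes with a mean log2 signal above 7 there, 24 were lower with both kits, with a median of -1.23 (quartiles -1.49 and -0.82). Among them Tff3, Olfm4 and Muc2, genes of goblet and crypt cells, were at -1.74, -1.69 and -1.44 log2. Apoa1 and Fabp2, genes of absorptive cells, were at -0.10 and -0.40, being the 2 exceptions. Fabp1 and Apoa4, also genes of absorptive cells, were at -0.81 and -0.42 and lower with both kits. A lower purity for every other cell type would move T cell, stromal, granulocyte and red cell genes alike. Only 8 of these lay above that level, 7 of them from the T and NK cell list; their median of -0.62 (quartiles -0.75 and -0.25) lay 0.617 above that of the epithelial genes, and the quartiles of the 2 sets did not overlap. They overlapped above a level of 6 (18 genes, median -0.62, quartiles -0.90 and -0.22, against 36 epithelial genes, median -1.17, quartiles -1.46 and -0.61) and of 8 (4 genes, median -0.82, quartiles -1.05 and -0.35, against 13, median -1.29, quartiles -1.58 and -0.81). Ccl5 was at -1.05 and Prg2 at -1.43. Epithelial carryover and lower purity cannot be told apart from a difference between the IgA cells themselves, because the test of purity turns on the level chosen and on few genes, and the mix of epithelial cells is not known. Both gene sets were also chosen by their level in the CD11b-negative arrays, which by itself favours lower values in the CD11b-positive ones. Over all tested members the medians were -1.14 for epithelial, -0.51 for T and NK cell, -0.37 for granulocyte, -0.18 for red cell and -0.15 for stromal genes. A gate on IgA would remove cells without it, but Krt8 still had signals of 952 and 914 in the CD11b-negative arrays. The gate therefore does not settle where such transcripts came from.

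Itgam was higher by 2.59 log2. Myeloid cells carried into the CD11b-positive gate would bring their abundant transcripts, and the 34 macrophage, monocyte and dendritic cell genes without Itgam had a median of 0.277 (quartiles -0.11 and 0.67), with 24 higher. Il1b, Apoe and C1qb were at 1.52, 1.10 and 1.16, Lyz2 at 0.51, and Csf1r, Adgre1 and Tyrobp at -0.11, -0.11 and 0.02. Members went both ways and several had a high level in the CD11b-negative arrays, which would hide a small share, so myeloid carryover and expression by the IgA cells themselves cannot be told apart.

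The 4 arrays make 3 splits into pairs, too few for a share under 0.05. By the rule of size the fractions gave 92 genes, the split by labelling kit 166 and the crossed split 27, so 2 of the 3 splits gave at least 92. The split by kit follows a technical batch. With the kit as a block, limma called 996 genes between the fractions and 0 for the crossed split. These 2 counts are not independent. With the kit blocked, the residual of the fraction fit is the crossed contrast, and that of the crossed fit is the fraction contrast. The 0 is therefore no separate control for the 996.

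A hypothesis of younger plasmablasts in the CD11b-positive fraction would let MHC class II genes be higher there, since these are lost as plasma cells mature. The 8 measured had a median of 0.0013 log2, from -0.63 to 0.59, with 4 higher, H2-Aa (0.59) and Cd74 (0.45) among them and H2-DMa at -0.63. This decides nothing either way.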
